A study of Mus musculus with 14 samples.

How the data were processed

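Gene expression was measured by 1-colour (Cy3) hybridisation of amplified RNA to Agilent mouse oligonucleotide arrays, with 14 arrays in 4 groups. Per the labels, the cells came from male mice that carry a fluorescent reporter at the Arginase-1 locus. Brain leukocytes were prepared by enzymatic digestion and a Percoll step, and blood mononuclear cells by a ficoll step. The cells were then sorted with antibodies against CD45, CD11b, Ly6G and F4/80 and a dead-cell stain. RNA was amplified with a whole transcriptome kit before labelling. The labels give replicate numbers but do not state whether replicates are separate animals, so every p-value measures only the spread between samples, part of which may be technical.

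The deposited scanner files hold, per the file headers, the output of Feature Extraction 10.7.3.1 for each array: a processed signal intensity (background-subtracted and detrended, not scaled between arrays, below 0 for some dim spots), median spot and local background intensities, and other values such as 0 or 1 flags per spot. A second deposited table holds the authors' log2 values. Compared with the scanner files, those log2 values had the ranks of the median spot signal within each array and nearly the same distribution in every array, as after quantile normalization without background subtraction. The authors name limma without a version or a step.

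The processed signal of each array was divided by that array's 75th percentile over non-control probes and log2 transformed, after ratios under 0.05 were raised to 0.05, so that the lowest possible value is -4.32. Spots that the scanner software called non-uniform or population outliers were set to missing. Of 41174 probes, 464 had fewer than 2 usable arrays in a group and 13105 were well above background on fewer than 3 of the 14 arrays. The remaining 27605 probes were named through their RefSeq accessions with a table made on the assembly GRCm38.p6, used for names only. The array's own annotation was made on mm9, and no positions are given. That table named 24844 of the 41174 probes (17178 symbols) and left 16330 without a symbol, and genes whose only probes are among those were not analysed here. The brightest kept probe stood for each of the 4415 symbols with 2 or more kept probes, and each unnamed probe was kept on its own, which left 21967 tested features, called genes below, of which 12963 carried a symbol. Probes of close paralogs (the Ear, Ifit3, H2 and Mt families) can take up each other's RNA, and the labelling kept no record of strand.

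All 14 arrays entered 1 limma fit on the 4 groups (lmFit and eBayes with an intensity trend, 10 residual degrees of freedom, two-sided). Adjusted p-values are Benjamini-Hochberg values from limma per comparison, and a gene was called at an adjusted p under 0.05. The comparisons, the test, the filters, 18 gene lists of biology, 12 lists of cell type markers and most alternatives were chosen before the data were examined. Each list was tested against all other genes with camera at a preset correlation of 0.01 between its genes, with missing values filled by the group mean, and again with the correlation estimated from the residuals. List p-values were adjusted over the lists of the same kind. Counts over a list are also given adjusted over the list alone. A list's median uses the fitted values of every tested member.

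Genes named in the text are those that a rule set in advance picked: per main comparison up to 10 called genes with a symbol in each direction, with the largest changes and no overlap between the arrays of both sides. Added to these were up to 4 called members of each list and a fixed set of macrophage activation genes (Arg1, Mrc1, Chil3, Retnla, Nos2, Il12b, Il1b, Tnf and Ccr2). Of the genes the rule picked, 5 are left out of the text and of the search for outlying arrays. Genes outside the rule are marked as chosen after their values were seen. Where no array of a side was well above background for any probe of a gene, the change is given as at least N-fold, computed from the other side's mean against the dim side's mean after each of its values was raised to the lowest level at which any probe was well above background on that array. Values after ± are standard errors of the fitted log2 difference.

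The 75th percentile of the processed signal lay between 119.4 and 418.5 across arrays, 50.4% to 68.69% of probes were well above background, no spot was saturated, and 200 to 728 spots per array were set aside. The number of arrays, 3 or 4 per group, limits the precision. The pipeline was tested on simulated data with 200 genes changed among 21967. With a log2 change of 2, between 85% and 91% of the changed genes were called, depending on the comparison, and with a log2 change of 1 between 25% and 50%. The share of false calls was 3.6% to 6.8%. The simulated noise was independent between genes and between arrays, with no slide effect and no floor. The real arrays have a structure by slide, so these shares need not hold for them.

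The arrays sat on 4 slides. Slides 1 to 3 each held 1 array of every group and slide 4 held 1 array of each brain group, so the slide could be fitted as a block. Alternatives were a normexp correction (offset 50) with quantile normalization, which used the median spot signal because the files hold no mean signal, quantile normalization alone, centring on the median, no filter and a stricter filter on dim probes, the mean of all probes of a gene, slide as a fixed or a random block, replicate number as a block, only the arrays compared, array weights, no intensity trend, the authors' values, normal monocytes as the reference, stricter thresholds, and each array left out in turn. A floor of 0.02 or 0.1, and leaving post-TBI monocyte replicate 4 out of comparisons it is not part of, were added after seeing the data. The fourth replicate of each blood group named in the series description is not among the deposited arrays.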

Results

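Macrophages from the injured mouse brain and monocytes from blood were profiled on 14 arrays to ask how brain macrophages that express arginase-1 differ from those that do not, and how both relate to blood monocytes. Traumatic brain injury (TBI) was inflicted by controlled cortical impact, a piston strike on the exposed cortex, and cells were collected 1 day later. The groups were Arg1+ brain macrophages (n = 4), Arg1- brain macrophages (n = 4), blood monocytes after TBI (n = 3) and blood monocytes from normal mice (n = 3), separated for arginase-1 by a fluorescent reporter. The 75th percentile of the processed signal, the measure of brightness of an array, ran from 119.4 to 418.5, and 50.4% to 68.69% of probes were well above background. Arrays of brain and blood cells correlated across genes at Pearson r 0.827 to 0.914, Arg1+ with Arg1- arrays at 0.934 to 0.975, and post-TBI with normal monocytes at 0.941 to 0.986. Within groups r was 0.962 to 0.979 for Arg1+ cells, 0.951 to 0.983 for Arg1- cells, 0.933 to 0.983 for post-TBI monocytes and 0.971 to 0.983 for normal monocytes. Genes are not independent replicates, so these values only describe the arrays.

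**Figure D1:**
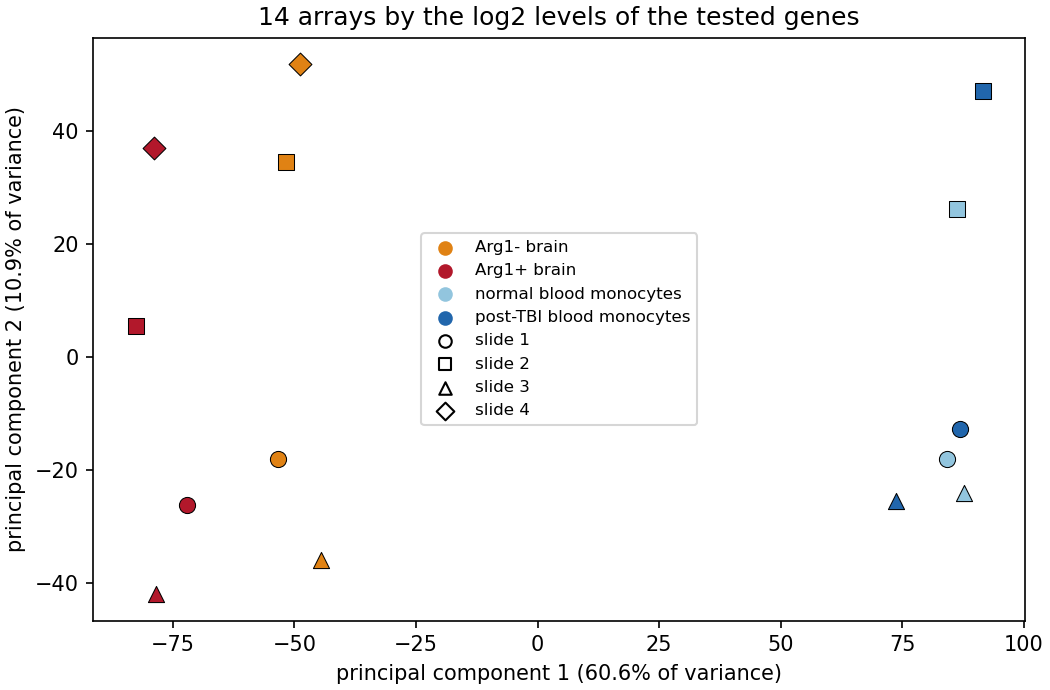
Principal components of all 14 arrays, with component 1 (60.64% of the variance) on the horizontal axis and component 2 (10.88%) on the vertical axis, 1 point per array, coloured by group and with a marker shape per slide. Component 1 parts brain from blood cells, and component 2 is positive for every array of slides 2 and 4 and negative for every array of slides 1 and 3.

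The first comparison asked what parts Arg1+ from Arg1- brain macrophages. Arg1+ cells carried more RNA for the chemokine Ccl24 (log2 difference 2.88 ± 0.33, n = 4 and 4, limma adjusted p = 0.000126), the scavenger receptor Cd36 (2.21 ± 0.24, adjusted p = 8.28e-05) and the secreted matrix protein osteopontin, Spp1 (1.60 ± 0.19, adjusted p = 0.000167). They carried less RNA for the machinery that presents antigen to helper T cells, led by its master regulator Ciita (-4.10 ± 0.30, adjusted p = 6.03e-06) and the class II chain H2-Aa (-3.22 ± 0.36, adjusted p = 0.000109). The lymph-node homing receptor Ccr7 (-4.48 ± 0.43, adjusted p = 3.02e-05) and the neutrophil granule peptide Camp (-4.73 ± 0.68, adjusted p = 0.000753) were lower as well. Arg1 itself was higher by 3.25 ± 0.43 (adjusted p = 0.000526, with 3 of the 4 Arg1+ spots usable). Because its reporter was the criterion of the sort, that value checks the sort and is no independent finding. Arg1 RNA was also present in Arg1- cells, whose 4 arrays averaged 3.16 on the log2 scale, against -3.49 in post-TBI monocytes.

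In total 1108 of 21967 genes were called in this comparison, 470 higher and 638 lower in Arg1+ cells. Those with a symbol were 398 higher and 362 lower. The arrays of the 2 sides did not overlap for 1069 of the called genes. Among all tested genes that share was 14.87%, where chance gives 2.86%. With slide fitted as a block 1502 genes were called, and 1096 of the 1108 differed in the same direction on each of the 4 slides. Genes without overlap must do so, and all were called on these same arrays, so this agreement adds no separate support. The count was 602 without Arg1- replicate 3, 698 without Arg1+ replicate 3 and, in a setting chosen after seeing the data, 1790 without post-TBI monocyte replicate 4, which enters here only through the shared spread.

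**Figure D2:**
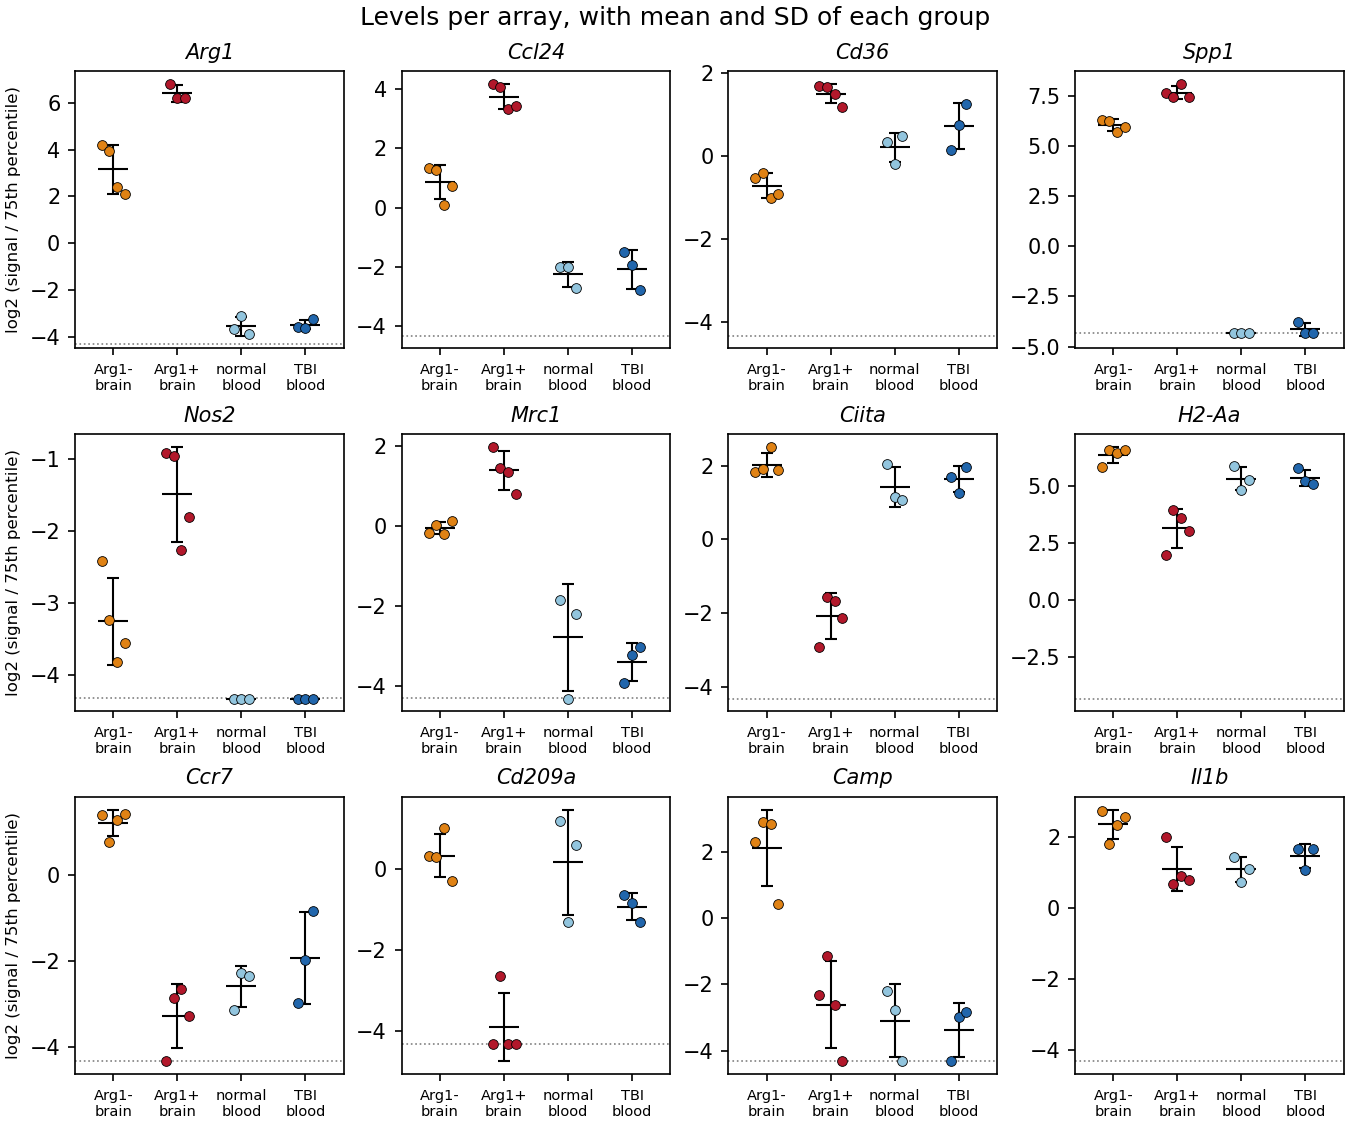
Log2 level of 12 genes relative to each array's 75th percentile, 1 point per array, in the 4 groups, with a line at the group mean, whiskers for its standard deviation and a dotted line at the floor of -4.32. Ccl24, Cd36 and Spp1 lie higher and Ciita, H2-Aa, Ccr7, Cd209a and Camp lower on every Arg1+ array than on any Arg1- array.

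Genes on the list of alternative activation went both ways. Alternative activation is the state that the cytokine IL-4 induces in macrophages, but the list is not limited to genes known from IL-4. Of 19 measured genes 4 were higher and 5 lower in Arg1+ cells (7 and 6 when adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.805). This list holds Arg1, the sorting gene, and Cd209a, which is also on the dendritic cell list, where 6 of 7 measured genes were lower. Ccl24 and the haemoglobin receptor Cd163 (1.39, above background on 2 of 4 Arg1- arrays) were higher. The lectin Cd209a (-4.22 ± 0.49, above background on 1 of 4 Arg1+ arrays) and the chemokine Ccl17 (-3.17 ± 0.28) were lower. Ccl22, whose product shares a receptor with that of Ccl17, was at least 7.32-fold lower and Retnla at least 4.0-fold lower. The Retnla call was lost without Arg1- replicate 4 (adjusted p = 0.0544). The mannose receptor Mrc1 (1.45, adjusted p = 0.0667) and Chil3 (-0.69, adjusted p = 0.147) did not pass, although Mrc1 did with slide as a block. The median of this list was 0.23 and its mean -0.19, and the set test pointed upward, but downward with quantile normalization (mean -0.31).

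The list of classical activation, the state driven by interferon gamma and bacterial products, was not called either (2 higher and 3 lower of 18, adjusted over the list alone 2 and 4, adjusted p = 0.205). Nos2, the inducible nitric oxide synthase, which competes with arginase for arginine, was higher in Arg1+ cells by 1.77 ± 0.32 (adjusted p = 0.00484, above background on 2 of 4 Arg1- arrays). The inflammatory cytokine Il1b was lower (-1.27 ± 0.29, adjusted p = 0.0178) with overlapping arrays. Its call was lost without any of Arg1- replicates 1, 3 and 4 or Arg1+ replicates 2, 3 and 4, with adjusted p up to 0.0639. Tnf did not differ detectably (0.27, adjusted p = 0.799, with -0.01 to 0.45 when single arrays were left out). Il12b had no named probe and was not analysed here. Among 19 genes of arginine and polyamine metabolism, which again include Arg1 and Nos2, 4 were higher and 1 lower (4 and 3 when adjusted over the list alone). The arginine transporter Slc7a2 (0.95) and the second arginase Arg2 (1.37, adjusted p = 0.00379) were among those higher. The call of this list (adjusted p = 0.033) was lost with an estimated correlation (adjusted p = 0.0873) with slide as a block (adjusted p = 0.0702) and with quantile normalization (adjusted p = 0.15).

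Chemokines as a group were higher in Arg1+ cells, with 8 of 27 measured genes higher and 2 lower (11 and 2 when adjusted over the list alone, median 0.46, adjusted p = 1.13e-04, but adjusted p = 0.0501 with an estimated correlation). The neutrophil attractant Cxcl3 (2.35 ± 0.35) and the platelet chemokine Ppbp (2.72 ± 0.43) followed Ccl24 in size. Chemokine receptors were lower as a group (0 higher and 3 lower of 18, adjusted over the list alone 0 and 4, adjusted p = 0.00774, and 0.0345 with an estimated correlation). The 3 were Ccr3, which is grouped with eosinophil genes further on, Ccr7, which is also a dendritic cell marker, and Cxcr2, also a neutrophil marker. The dendritic cell and neutrophil marker lists were both lower, the neutrophil list only with the preset correlation. Ccr2, the receptor that draws monocytes into tissue, did not pass (adjusted p = 0.0602, with log2 differences of -1.22 to -0.84 when single arrays were left out). It passed without Arg1+ replicate 2 (adjusted p = 0.027) and with slide as a block.

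Lysosome and phagocytosis genes showed 11 of 32 measured members higher and 1 lower (19 and 1 when adjusted over the list alone, median 0.56, adjusted p = 7.47e-15, and 0.00112 with an estimated correlation). Besides Cd36, the proton pump subunit Atp6v0d2 was at least 3.1-fold higher, while the receptor for dying cells Axl was lower (-1.57 ± 0.23). Glycolysis and hypoxia genes had 9 of 27 members higher and 0 lower (16 and 2 when adjusted over the list alone, median 0.66, adjusted p = 7.06e-11, and 0.0134 with an estimated correlation). Examples are the collagen hydroxylase P4ha2 (2.51 ± 0.30, above background on 3 of 4 Arg1- arrays) and the oxygen-sensing enzyme Egln3 (1.86 ± 0.36, adjusted p = 0.00646). Genes of heme, iron and oxidative defence had 8 of 23 higher and 1 lower (11 and 3 when adjusted over the list alone, median 0.59, adjusted p = 1.16e-06, and 0.00606 with an estimated correlation). Among them were Blvrb, which handles a breakdown product of heme (1.28 ± 0.24), and, as the 1 lower gene, Lcn2, which is also on the neutrophil list (-3.34 ± 0.67). Repair and matrix genes had 5 of 30 higher and 0 lower (also 5 and 0 when adjusted over the list alone, adjusted p = 2.01e-05, and 0.027 with an estimated correlation). They included Spp1 and the elastase Mmp12 (1.43 ± 0.22, above background on 1 of 4 Arg1- and 3 of 4 Arg1+ arrays). With quantile normalization these 4 lists kept their calls with smaller medians. Lysosome genes had 7 higher and 1 lower (10 and 1 over the list alone, median 0.34), and glycolysis and hypoxia genes 4 and 1 (9 and 2, median 0.47). Heme, iron and oxidative defence had 6 and 1 (10 and 3, median 0.49) and repair and matrix genes 5 and 0 (median 0.16, against 0.28).

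The genes of antigen presentation by class II molecules had the largest median difference of the 18 biology lists. Of 13 measured, 11 were lower in Arg1+ cells and 0 higher (the same counts when adjusted over the list alone, median -2.42, adjusted p = 2.54e-18, and 0.00606 with an estimated correlation). Within slides 1 to 4 the list median was -3.25, -1.73, -2.65 and -2.50. H2-DMb2, part of the chaperone that loads peptides (-3.27 ± 0.35), and H2-Ob, part of its inhibitor (-3.22 ± 0.46), were lower beside Ciita and H2-Aa. Dendritic cell markers were lower beside them, 6 of 7 measured (0 higher, the same counts when adjusted over the list alone, median -2.26, or -2.06 with genes below background at their bound, adjusted p = 6.47e-12, and 0.00124 with an estimated correlation). The growth factor receptor Flt3 (-2.50 ± 0.29, above background on 1 of 4 Arg1+ arrays) and Kmo (at least 4.16-fold lower) are examples.

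Markers of neutrophils were lower in Arg1+ cells for 8 of 14 measured genes and higher for 1 (10 and 1 when adjusted over the list alone, median -2.52, or -2.45 with bounds, adjusted p = 2.52e-09, but adjusted p = 0.099 with an estimated correlation). Beside Camp, the granule proteins Ngp (-4.38 ± 0.59) and Ltf (-4.27 ± 0.72) and the calcium-binding S100a9 (-4.00 ± 0.74) were lower, while the collagenase Mmp8, named after its values were seen, was higher (0.98). Genes of the patrolling Ly6C-low monocyte were lower for 8 of 16 and higher for 0 (10 and 1 when adjusted over the list alone, median -0.96, or -0.86 with bounds, adjusted p = 3.76e-09, and 0.00388 with an estimated correlation). Spn (-1.85 ± 0.22) and the integrin Itgal (-1.54 ± 0.13) are examples. Genes of the inflammatory Ly6C-high monocyte were lower for 5 of 15 and higher for 0 (8 and 0 when adjusted over the list alone, adjusted p = 2.01e-05, but adjusted p = 0.056 with an estimated correlation). Plac8 (-1.58 ± 0.21) and Ly6c2 (-1.01 ± 0.20) were among these.

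Calls of the next lists held only with the preset correlation. Cholesterol synthesis genes were lower for 4 of 22, higher for 0 (6 and 0 when adjusted over the list alone, adjusted p = 1.02e-05, but adjusted p = 0.0666 with an estimated correlation). Among them was Cyp51 (-1.70 ± 0.20), an enzyme of the later steps. Proliferation genes were lower for 6 of 28, higher for 0 (7 and 0 when adjusted over the list alone, adjusted p = 1.29e-05, but adjusted p = 0.056 with an estimated correlation). They were led by the topoisomerase Top2a (-1.71 ± 0.35). None of 32 interferon-stimulated genes was called over all genes or adjusted over the list alone. Their median was -0.38 with adjusted p = 1.29e-05, and adjusted p = 0.229 with an estimated correlation. Lipid handling genes were higher as a group (3 higher, 2 lower of 19, the same when adjusted over the list alone, adjusted p = 0.00774, but adjusted p = 0.0666 with an estimated correlation). The cholesterol exporter Abca1 (1.11 ± 0.20) and the fatty acid binding protein Fabp4 (1.17 ± 0.22) were higher and Cyp27a1 (-1.02 ± 0.21) lower. Feedback genes of NF-kB signalling were not called as a list (0 higher and 3 lower of 23, adjusted over the list alone 2 and 5, adjusted p = 0.0546), with Traf1 (-2.42 ± 0.20) among the lower ones. Nor were immediate early and stress genes (0 higher and 2 lower of 29, adjusted over the list alone 1 and 2, adjusted p = 0.189). With quantile normalization both were called downward, NF-kB feedback with adjusted p = 0.00392 (0 and 2 called, 1 and 7 over the list alone) and immediate early genes with adjusted p = 0.0119 (0 and 2, median -0.32). The median of lipid handling genes fell from 0.29 to 0.14 there (adjusted p = 0.0293).

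Markers of other cells gave smaller differences. Microglia markers were called upward as a list with 0 of 11 genes called (median 0.38, adjusted p = 0.0256, but adjusted p = 0.529 with an estimated correlation, 0.0679 with quantile normalization and 0.0517 without post-TBI replicate 4). Neuron markers were called upward with 1 of 11 genes higher, Nefl (1.02 ± 0.22, adjusted p = 0.00838 for the list, but adjusted p = 0.529 with an estimated correlation). Natural killer cell markers were called downward with 2 of 10 lower (adjusted p = 0.0186, but adjusted p = 0.529 with an estimated correlation), among them Klrd1 (-3.55 ± 0.44, above background on 1 of 4 Arg1+ arrays). Lists of T cells (1 higher of 9, adjusted p = 0.305), B cells (1 higher of 9, Cd22 at 0.97, adjusted p = 0.808) and red cells (0 of 5, adjusted p = 0.808) were not called. Nor were platelets (1 higher of 9, Ppbp, adjusted p = 0.808), oligodendrocytes (0 of 7, adjusted p = 0.524) and endothelium (0 of 7, adjusted p = 0.808). Astrocyte markers had 1 higher of 9, Gja1 at 1.17 (above background on 1 of 4 Arg1- and 3 of 4 Arg1+ arrays), and the list was not called (adjusted p = 0.0623), except upward with quantile normalization (adjusted p = 0.0391). For B cells (median -0.03, mean 0.03), platelets (-0.03 and 0.16) and endothelium (-0.11 and 0.03) the median and mean differed in sign.

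**Figure D3:**
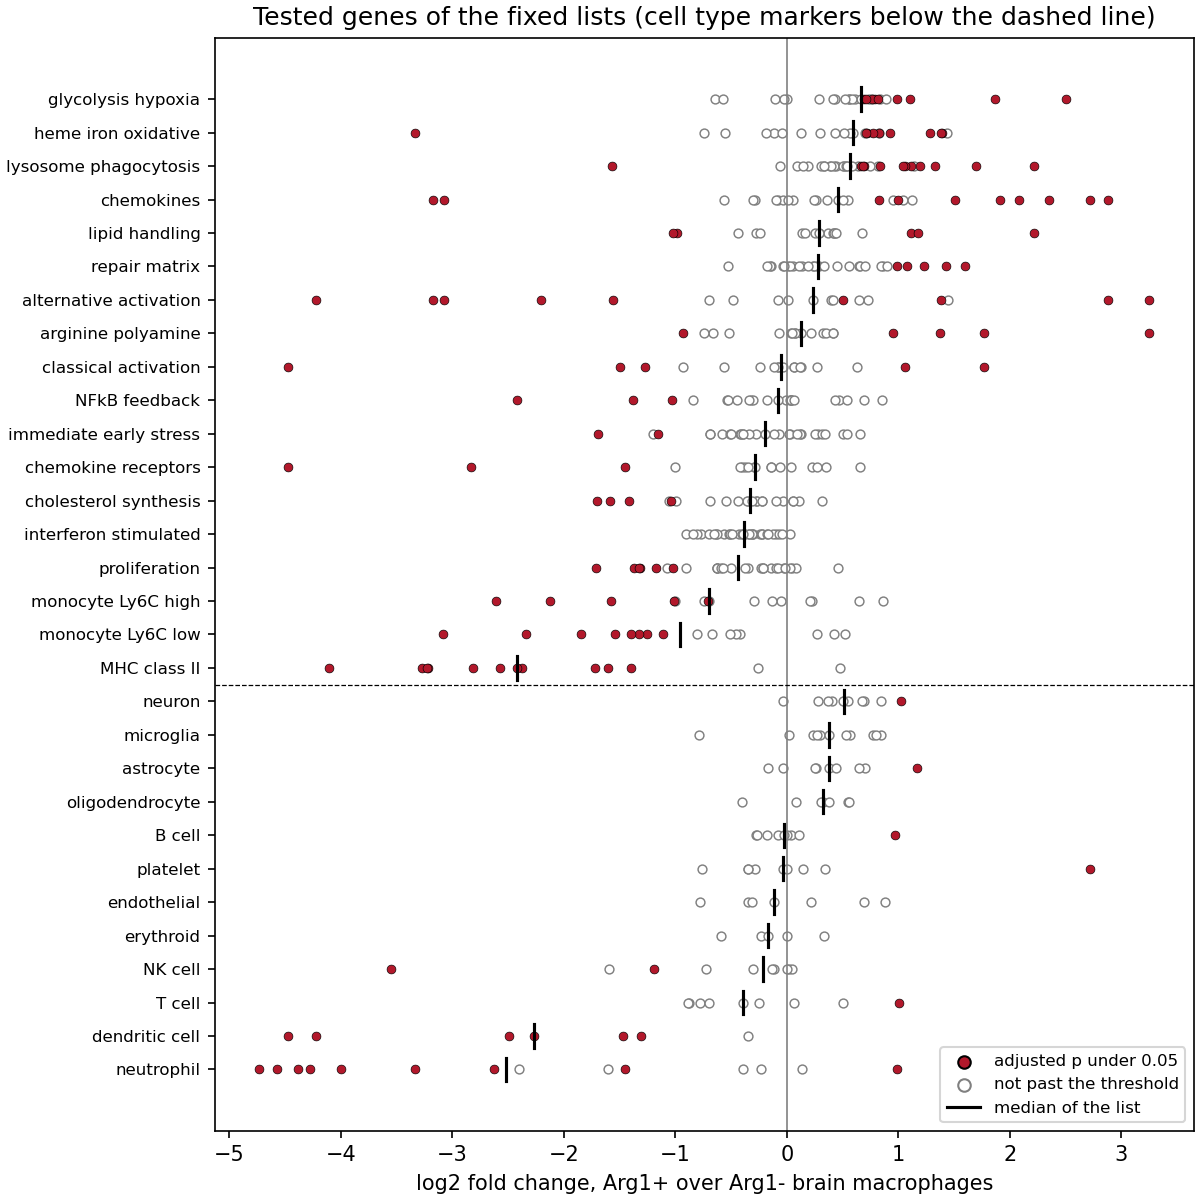
Fitted log2 difference of each member of the fixed gene lists between Arg1+ and Arg1- brain macrophages on the horizontal axis, 1 point per gene and 1 line per list, with a tick at the list median and marker lists below the dashed line. Genes at the floor are drawn at their fitted value, and the lists of class II presentation (median -2.42), neutrophil (-2.52) and dendritic cell markers (-2.26) lie farthest to the left and glycolysis and hypoxia genes (0.66) to the right.

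The second comparison asked how circulating monocytes of injured mice differ from those of normal mice. No group had the surgery without the impact, so the injury and the surgery cannot be told apart here. Few genes passed. Higher after TBI was Fkbp5, a chaperone partner of the glucocorticoid receptor that glucocorticoids induce (1.55 ± 0.17, n = 3 and 3, limma adjusted p = 0.0025). So were the matrix proteoglycan Vcan (1.96 ± 0.29, adjusted p = 0.0134) and the neutrophil attractant Cxcl2 (2.58 ± 0.40, adjusted p = 0.0191, above background on 1 of 3 normal arrays). Lower were the interferon-induced Ifit3 (-2.48 ± 0.41, adjusted p = 0.0241) and its paralog Ifit3b (-2.51 ± 0.43, adjusted p = 0.0344, above background on 2 of 3 post-TBI arrays), whose probes may read each other's RNA. In total 33 genes were called, 24 higher and 9 lower after TBI, of which 17 and 7 carried a symbol.

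Interferon-stimulated genes had the smallest list p-value. Only Ifit3 of 32 measured was called over all genes, while 17 were lower and 1 higher when adjusted over the list alone, with a median of -0.79 (adjusted p = 2.71e-23, but adjusted p = 0.152 with an estimated correlation). On slides 1, 2 and 3, which each held 1 array of either blood group, the list median was -1.09, -0.40 and -0.99. The list of Ly6C-high monocytes was called upward (2 higher of 15, adjusted over the list alone 4, adjusted p = 0.0126, but adjusted p = 0.418 with an estimated correlation) through Vcan and the lectin receptor Clec4e (1.20 ± 0.20). Its median was only 0.05, with a mean of 0.39. Platelet markers were higher after TBI as a list, with 0 of 9 called and 4 higher when adjusted over the list alone (median 0.87, adjusted p = 7.2e-07, but adjusted p = 0.178 with an estimated correlation). Red cell markers, with 0 of 5 called and 4 higher when adjusted over the list alone (median 1.66, adjusted p = 3.1e-04, but adjusted p = 0.184 with an estimated correlation), were higher as well. Within slides 1 to 3 the red cell median was 3.11, 2.46 and -0.61, so its direction did not hold on every slide. The platelet median was 1.76, 1.37 and 0.46.

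Natural killer cell markers were lower as a list (median -0.56, adjusted p = 0.00383, but adjusted p = 0.477 with an estimated correlation). Higher as lists were B cell markers (median 0.41, adjusted p = 0.00383, but adjusted p = 0.184 with an estimated correlation) and T cell markers (0.39, adjusted p = 0.0482, but adjusted p = 0.282 with an estimated correlation). Proliferation genes were called too (0.16, adjusted p = 0.0349, but adjusted p = 0.443 with an estimated correlation). Without post-TBI replicate 4 the T cell (adjusted p = 0.0721) and proliferation lists (adjusted p = 0.303) lost their calls. In each of these lists 0 genes were called over all genes. For the other lists the smallest adjusted p was 0.0588, for heme, iron and oxidative defence. Median and mean differed in sign for class II presentation (0.035 and -0.005), lipid handling (-0.002 and 0.13), NF-kB feedback (-0.03 and 0.11), Ly6C-low monocytes (-0.06 and 0.03) and neutrophils (-0.15 and 0.17), none of which was called.

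The 33 genes rested on single arrays and on the other groups' spread. The count was 2 without post-TBI replicate 3, 16 without replicate 4, 60 without replicate 1, 10 without normal replicate 2 and 54 without normal replicate 3, and limma on these 6 arrays alone called 0 (893 at an unadjusted p under 0.05). Array weights gave 314, with post-TBI replicate 3 weighted 4.75, replicate 1 0.82 and replicate 4 0.22. On the post-TBI side that count thus leans mostly on replicate 3. Of the 19 genes named by rule, only Fkbp5 kept its call in all 6 fits with 1 array left out. Vcan and Clec4e were lost without normal replicate 2 or 4 or post-TBI replicate 3 or 4 (adjusted p up to 0.0942 and 0.13). Cxcl2 was lost without normal replicate 2 or post-TBI replicate 3 or 4 (up to 0.122). The call of Ifit3 was lost without normal replicate 2 or 3 or post-TBI replicate 3 (up to 0.122), and that of Ifit3b without those or post-TBI replicate 4 (up to 0.164). With slide as a block 32 genes were called. The arrays did not overlap for any of the 33, as for 9.26% of all tested genes, where chance gives 10%. Without overlap all 33 had to differ in the same direction on each of the 3 slides, so that agreement adds no support.

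The third comparison set both brain populations, averaged, against post-TBI monocytes of the same injury state. Brain macrophages carried far more RNA for osteopontin, Spp1 (10.98 ± 0.18, adjusted p = 8.18e-15, above background on 1 of 3 blood arrays). The same held for the membrane glycoproteins Gpnmb (8.33 ± 0.42) and Stab1 (7.89 ± 0.26), the endocytic adaptor Dab2 (8.24 ± 0.25) and podoplanin, Pdpn (at least 527-fold). Arg1 was higher in brain cells by 8.27 ± 0.39, above background on 2 of 3 blood arrays. Lower in brain cells were the heme synthesis enzyme of red cell precursors Alas2 (-7.50 ± 0.50, adjusted p = 1.81e-08), the angiotensin-converting enzyme Ace (-5.92 ± 0.39) and Cd300e (-5.89 ± 0.29), both genes of the patrolling monocyte. In total 9023 genes were called, 4507 higher and 4516 lower.

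With slide as a block 9948 genes were called, and 8794 of the 9023 differed in the same direction on each of the 3 slides that held brain and post-TBI blood arrays. That agreement was counted on the arrays that gave the calls, so it is no separate support. The arrays of both sides did not overlap for 29.22% of tested genes, where chance gives 1.21%, and for 6237 of those called. Brain cells passed through digestion at 37 °C and a different density step from blood cells, so tissue and preparation cannot be told apart in this comparison.

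Alternative activation genes were higher in brain cells for 14 of 19 measured and lower for 2 (the same when adjusted over the list alone, median 1.84, adjusted p = 1.12e-06, and 0.0171 with an estimated correlation). Mrc1 (4.07 ± 0.41) and Ccl24 (4.38 ± 0.31) were higher and Chil3 (-1.53 ± 0.24) lower. Retnla did not pass (-0.86, adjusted p = 0.168), except without post-TBI replicate 4 (-1.40). Classical activation genes split into 10 higher and 5 lower of 18 (11 and 5 when adjusted over the list alone, adjusted p = 0.0671, but adjusted p = 0.0348 without post-TBI replicate 4). The cytokines Tnf (3.44 ± 0.33, adjusted p = 7.88e-07) and Il1a (3.99 ± 0.28) and Nos2 (at least 3.88-fold) were higher, while Il1b did not pass (0.26, adjusted p = 0.51). Chemokines were higher for 16 of 27 and lower for 2 (the same when adjusted over the list alone, median 2.47, adjusted p = 6.15e-08, and 0.012 with an estimated correlation). Examples are Cxcl16 (4.75 ± 0.21), Cxcl3 (at least 99.4-fold) and the monocyte attractant Ccl12 (at least 41.8-fold). Chemokine receptors were not called as a list (2 higher and 6 lower of 18, adjusted p = 0.713). Ccr2 was lower (-0.87 ± 0.28, adjusted p = 0.0194) with overlapping arrays, and its call was lost without post-TBI replicate 1 or 3 (adjusted p up to 0.135).

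Lysosome and phagocytosis genes were higher for 24 of 32 and lower for 0 (26 and 0 when adjusted over the list alone, median 1.20, adjusted p = 4.24e-13, and 0.000891 with an estimated correlation). They included the receptor for dying cells Mertk (6.25 ± 0.18, above background on 1 of 3 blood arrays) and the tetraspanin Cd63 (5.82 ± 0.48). Repair and matrix genes (22 higher and 1 lower of 30, median 1.95, adjusted p = 1.17e-11, and 0.00257 with an estimated correlation) included the membrane protease Mmp14 (5.98 ± 0.16). Glycolysis and hypoxia genes (22 higher and 2 lower of 27, median 1.64, adjusted p = 3.65e-09, and 0.0173 with an estimated correlation) included the vessel growth factor Vegfa (4.51 ± 0.55) and Egln3 (4.46 ± 0.34). For these lists the counts were the same when adjusted over the list alone. Arginine and polyamine genes (14 higher and 1 lower of 19, adjusted over the list alone 15 and 1, median 0.93, adjusted p = 2.31e-06, and 0.00438 with an estimated correlation) included, beside Arg1, Arg2 (3.29 ± 0.23, above background on 2 of 3 blood arrays) and the arginine-making enzyme Ass1 (3.11 ± 0.24). The cystine transporter Slc7a11 was at least 42.0-fold higher, in a list of heme, iron and oxidative defence with 11 higher and 3 lower of 23 (adjusted p = 0.0151, but adjusted p = 0.0938 with an estimated correlation). Immediate early and stress genes (17 higher and 5 lower of 29, adjusted p = 0.00156, but adjusted p = 0.084 with an estimated correlation) included the transcription factors Jun (3.09 ± 0.20) and Egr2 (2.72 ± 0.20).

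Ly6C-low monocyte genes were lower in brain cells for 15 of 16 and higher for 0 (the same when adjusted over the list alone, median -3.22, adjusted p = 4.24e-13, and 0.000891 with an estimated correlation). Treml4 (-5.22 ± 0.26) was among them with Ace and Cd300e. Ly6C-high monocyte genes were lower for 9 of 15 and higher for 3 (the same when adjusted over the list alone, adjusted p = 0.00305, but adjusted p = 0.171 with an estimated correlation). Plac8 (-2.96 ± 0.19) was lower and the matrix protein Thbs1 (3.18 ± 0.41) higher. Not called as lists were interferon-stimulated genes (14 higher and 4 lower of 32, adjusted p = 0.057, but adjusted p = 0.0286 without post-TBI replicate 4), class II presentation (1 and 3 of 13, adjusted p = 0.311) and lipid handling (9 and 4 of 19, adjusted p = 0.405). Cholesterol synthesis (2 and 7 of 22, adjusted p = 0.35, median 0.06 and mean -0.20), NF-kB feedback (6 and 6 of 23, adjusted p = 0.843) and proliferation (7 and 6 of 28, adjusted p = 0.872) were not called either.

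Microglia markers were higher in brain cells for 8 of 11 and lower for 1 (9 and 1 when adjusted over the list alone, median 1.89, adjusted p = 5.26e-05, but adjusted p = 0.226 with an estimated correlation). Fcrls (5.89 ± 0.19), Olfml3 (5.01 ± 0.21) and Tmem119 (3.78 ± 0.17) were among them. Astrocyte markers were higher for 5 of 9 and lower for 1 (adjusted p = 0.0175, but adjusted p = 0.388 with an estimated correlation), with the glutamate transporter Slc1a2 at least 27.5-fold higher. Red cell markers were lower in brain cells for 4 of 5 (median -5.22, or -5.10 with bounds, adjusted p = 0.00126, but adjusted p = 0.226 with an estimated correlation). Platelet markers were lower for 7 of 9 (median -1.65, adjusted p = 3.31e-04, but adjusted p = 0.226 with an estimated correlation). B cell markers were lower for 8 of 9 (median -1.40, adjusted p = 3.31e-04, but adjusted p = 0.218 with an estimated correlation), and 0 genes of these lists were higher. The platelet integrin Itgb3 (-4.07 ± 0.41) and the B cell receptor subunit Cd79a (-2.83 ± 0.33) are examples. Markers of neutrophils (5 higher and 3 lower of 14, adjusted p = 0.415), natural killer cells (0 and 4 of 10, adjusted p = 0.172) and T cells (1 and 3 of 9, adjusted p = 0.529) were not called. Nor were those of dendritic cells (1 and 3 of 7, adjusted p = 0.505), neurons (3 and 1 of 11, adjusted p = 0.246), oligodendrocytes (1 and 1 of 7, adjusted p = 0.745) and endothelium (2 and 2 of 7, adjusted p = 0.742). Median and mean differed in sign for T cells (-0.21 and 0.01), oligodendrocytes (0.04 and -0.07) and endothelium (-0.71 and 0.40). The myelin gene Mbp was lower with its brightest probe (-2.55) but not with the mean of its probes (0.73, adjusted p = 0.105), so its direction depends on the probe.

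Each brain population was also compared with post-TBI monocytes on its own. In Arg1+ cells 8768 genes were called (4376 higher, 4392 lower) and in Arg1- cells 7332 (3740 higher, 3592 lower). With slide as a block the counts were 9889 and 8129. Both populations were higher for 3118 genes and lower for 3138, where independent lists would share 745 and 718, and 12 genes went in opposite directions. The correlation of both differences across genes was 0.918 (covariance 1.03). In 20 simulated sets without any change the shared monocyte arrays gave a correlation of 0.57, but with a covariance of 0.0611. With normal monocytes as the reference for Arg1- cells only, the shared counts were 2862 and 2877, with r 0.881. Class II genes parted the populations: 11 of 13 were lower than in post-TBI monocytes in Arg1+ cells (adjusted p = 9.08e-04, but adjusted p = 0.182 with an estimated correlation). In Arg1- cells 2 were higher and 0 lower (adjusted p = 0.0208, but adjusted p = 0.378 with an estimated correlation and 0.0707 with slide as a block). The difference itself is the one tested between Arg1+ and Arg1- cells above.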

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

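The tests behind the values in this part were planned, and none was chosen only after a result was seen. Among 326 groups of 4 arrays, each holding 1 gene or array measure, 15 had a single array whose gap to the nearest other array was larger than Dixon's criterion allows, and chance alone gives about 1 in 20, or 16.3. No explanation was weighed for them, and the values are log2 levels unless stated.

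In Arg1- cells, replicate 1 had a level of -3.80 for Adgre4, with the other arrays between -3.10 and -2.95. Replicate 2 stood apart for Dusp2 (1.39, others 2.40 to 2.50), Emp1 (4.04, others 3.52 to 3.55) and Fabp7 (-1.23, others -2.16 to -2.01). Replicate 3 stood apart for Ciita (2.52, others 1.82 to 1.92) and Tyms (-1.65, others -2.61 to -2.52), and 4.46% of its probes had a processed signal below 0, against 10% to 10.56% on the other arrays. Replicate 4 stood apart for Vwf (1.08, others 0.04 to 0.10).

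In Arg1+ cells, replicate 1 stood apart for Cxcl2 (4.52, others 2.99 to 3.18) and Il1b (2.01, others 0.67 to 0.90). Replicate 2 stood apart for Ccl7 (4.97, others 4.43 to 4.52) and Cyp51 (-1.28, others -1.82 to -1.73). Replicate 3 had a level of -2.55 for Rel (others -3.62 to -3.54), and replicate 4 stood apart for Cd163 (-3.00, others -2.49 to -2.44) and Dab2 (4.51, others 4.96 to 5.04).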

How the results depend on the processing

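Settings named here as added were chosen only after the data were seen; the others were planned. Arg1 in Arg1+ against Arg1- cells kept its sign and call under every setting run (2.901 to 3.595 with single arrays left out). The count for that comparison (1108) was 623 with a 2-fold minimum, 450 at adjusted p under 0.01, and 602 (without Arg1- replicate 3) to 1790 (without post-TBI monocyte replicate 4, added) with 1 array left out. For post-TBI against normal monocytes (33) it was 9 at adjusted p under 0.01, 15 with normexp correction, 54 with slide as a random block, 2 with replicate number as a block, 0 by limma with only the arrays compared (893 at an unadjusted p under 0.05), 314 with array weights, 20 with the authors' values and 2 to 60 with 1 array left out. With only the arrays compared, 4 residual degrees of freedom remain. With a 2-fold minimum the counts were 4893 for brain against blood, 5492 for Arg1+ and 4377 for Arg1- against blood, the last 4732 at adjusted p under 0.01. The other planned settings kept these counts within 1.5 times, with replicate number as a block included (833, 8307, 8091 and 6563). The labels do not say that replicate numbers pair samples. The best-correlated partner of a brain array carried its number for 2 of 8 arrays, and the 2 blood pairs of equal number correlated at 0.21 and 0.355, the latter on a shared slide. Higher calls after TBI were 72.7% of all calls, but 60% with the authors' values and with the added floor of 0.1. Of 1088 values of named genes in Arg1+ against Arg1- cells, 1032 kept sign and call under planned settings, 44 lost and 12 gained a call; for post-TBI against normal monocytes 162 of 247 kept and 85 lost it; for brain against blood 1688 of 1701 kept it. Mbp in brain against blood turned to 0.73 with the mean of all probes, which averages probes that differ, and Tnf in Arg1+ against Arg1- cells to -0.012 without Arg1- replicate 2 (range -0.012 to 0.45). List means turned, without any call, for Ly6C-low (-0.027) and neuron genes (-0.002) after TBI with quantile normalization, for oligodendrocytes in brain against blood with slide as a block (0.057), and, added, without post-TBI replicate 4 for proliferation (0.023) and oligodendrocytes (0.007) in brain against blood and neutrophils after TBI (-0.177). Of 90 list results, 27 lost their call with an estimated correlation, 2 lost and 3 gained one with quantile normalization, 1 lost one with slide as a block, and 3 lost and 2 gained one without post-TBI replicate 4 (added). The causes were not tested. With the stricter filter 6 values of named genes could not be had. Signal near background limits genes at the floor: only bounds are given where no array of a side was well above background, and where some were, the fitted difference depends on the floor (Cd209a log2 fold change, Arg1+ against Arg1- brain macrophages, -4.894 with a floor at 0.02 of the 75th percentile and -3.471 with a floor at 0.1 of the 75th percentile, both added).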

Other observations

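The genes in this and the next paragraph were picked after their values were seen. The tests of neutrophil, class II and interferon genes further on were chosen only after the result was seen, while the counts over other splits of the arrays were planned. Brain macrophages held much more RNA than post-TBI monocytes for the 3 chains of complement C1q, which starts the classical complement pathway. C1qa was higher by 6.44 ± 0.35 (log2), C1qb by 5.18 ± 0.22 and C1qc by 4.69 ± 0.32. Ms4a7 (4.33 ± 0.18) and the chemokines Ccl2 (3.28 ± 0.28), Ccl3 (3.26 ± 0.33) and Ccl4 (3.73 ± 0.33) were higher too. The microglia marker P2ry12 did not differ detectably (0.06, adjusted p = 0.918), Gpr34 did not pass (0.82, adjusted p = 0.0701) and P2ry13 was higher (1.89 ± 0.24). The result for P2ry12 rests on the post-TBI reference. Its level was -1.21 in Arg1+ and -1.50 in Arg1- cells, -1.42 in post-TBI and -3.23 in normal monocytes. The blood groups did not differ past the threshold (limma adjusted p = 0.187).

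Within the brain, Arg1+ cells had more RNA for the metal-binding metallothioneins Mt1 (1.22 ± 0.21, limma adjusted p = 0.00295) and Mt2 (2.31 ± 0.32) and for the hypoxia-induced lipid droplet gene Hilpda (1.39 ± 0.29). They had less for Ear1 (-3.18 ± 0.24, adjusted p = 6.03e-06) and Prg2 (-3.07 ± 0.70, adjusted p = 0.0182, above background on 1 of 4 Arg1+ arrays). Ccr3 was at least 6.38-fold lower, a call lost without any of Arg1- replicates 1, 2 and 3 or Arg1+ replicates 2, 3 and 4 (adjusted p up to 0.0635). Ear1, Prg2 and Ccr3 stand for a group of genes named after eosinophil granules and receptors. Its members were put together after they were seen to be lower in Arg1+ cells, so their shared direction is no test. Other cells in the Arg1- sort were not tested as their source. Ear1 was more abundant in the sorted blood monocytes (5.76 after TBI) than in Arg1- cells (1.63), and Ear paralogs share sequence. So were Ear6 (2.9 against -1.0), Ear10 (4.8 against 0.1) and Rnase2a (5.1 against 0.4) of this group. Ccr3 and Alox15 also had the higher mean in post-TBI blood, and Prg2 the lower (-2.4 against -0.8). The group is thus not particular to eosinophils in these samples. The cell fusion genes Dcstamp and Ocstamp and the transcription factor Irf4 were at least 6.98-, 7.38- and 6.9-fold lower in Arg1+ cells.

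For Arg1+ against Arg1- cells, 2 of the 35 splits of the 8 arrays into 4 and 4 gave as many genes as the real 1108, so these splits do not exclude chance. The other split, with 1746 genes, sets slides 2 and 4 against slides 1 and 3, which points to a structure by slide, since the other splits along whole slides gave 0. With slide as a block the real split gave 1502, and among the 8 splits that keep 1 array of each slide on either side the highest other gave 2, though 8 splits are too few for a share under 0.05. For post-TBI against normal monocytes the real split gave 33 and the highest other of 10 gave 4, which again are too few splits. Chance was argued against, at a share under 0.05, for brain against blood (1 of 100 splits, 9023 against at most 439) and for Arg1+ (1 of 35, 8768 against 4341) and Arg1- cells against blood (1 of 35, 7332 against 2291). These are the smallest shares that so many splits can give, and the comparisons use the same post-TBI arrays.

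The 8 neutrophil granule and receptor genes that were lower in Arg1+ cells could come from other cells in the Arg1- sort, but cells like the sorted blood monocytes are excluded for Camp, Ltf, Ngp and S100a9, where the lowest Arg1- array was at least 1.80 (log2) above the highest post-TBI monocyte array. Lcn2 was above the highest post-TBI array (2.28) on Arg1- replicates 1, 2 and 3 (2.46, 2.83 and 2.34) but not on replicate 4 (0.81). Replicate 4 would need 48.7% of such cells (29.7% with the brightest post-TBI array as the source). Over 15 Ly6C-low monocyte genes the median was 2.8% to 4.4% and the upper quartile at most 10.3%. However, Itgax needs 56.4% to 189.2% and Cx3cr1 up to 37.3%. Those 15 genes were also picked as lower in brain cells than in post-TBI monocytes, which favours low shares, so they cannot exclude such cells for Lcn2. Cells like the blood monocytes stay open for Lcn2, for Cxcr2 and Elane, which lie near the floor with overlapping arrays (lowest difference -0.25), and for Retnlg, which would need 13.2%, but only 5.2% with the brightest array. Neutrophils or their precursors cannot be told apart from a difference within macrophages: the marker list had 8 genes lower and Mmp8 higher, and the Ly6G gate should remove mature neutrophils. The camera adjusted p = 0.099 under an estimated correlation cannot decide it, because genes that move together between arrays raise this value. Camp, Ltf, Ngp and S100a9 were all lowest on Arg1- replicate 4 (0.43, 2.80, 2.71 and 2.10) and highest on replicate 2. A biological difference between Arg1+ and Arg1- macrophages stays open, as untested.

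The 11 class II genes lower in Arg1+ cells have a candidate source in dendritic cells in the Arg1- sort. Dendritic cell markers were lower too, 6 of 7 measured and 0 higher (adjusted p = 0.00124 under an estimated correlation), which is consistent with it. However, Cd209a, Ccr7 and Xcr1 also stand in other lists here and a gate on F4/80 and CD11b should remove dendritic cells that lack these proteins. Cells like the sorted blood monocytes are argued against. The share of them needed to supply the class II RNA had a median over the 11 genes of 134% or more on each Arg1- array, which no mixture can hold. With the mean post-TBI level as the source, single genes went down to 55.2% (H2-Eb2). With the brightest post-TBI array as the source the lowest median was 96.1%. The 15 Ly6C-low monocyte genes gave a median of 2.8% to 4.4%, and 1 of them, Itgax, reaches 134% on any array. Those 15 were picked as lower in brain cells than in post-TBI monocytes, which favours low shares. Lower class II expression by Arg1+ macrophages themselves stays open, as untested, and both may hold.

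The interferon-stimulated genes lower in post-TBI monocytes do not rest on 1 post-TBI array, as the list median was still negative with any of them left out (-0.75 without replicate 3, -0.99 without replicate 1 and -0.79 without replicate 4, preset adjusted p at most 6.56e-14). Each of the 3 slides held 1 array of either blood group, so a slide effect shared by both arrays cancels from this difference by design. The weakest of the 3 within-slide medians was -0.40. The list kept its call with slide as a block at the preset correlation (camera adjusted p = 2.97e-19). The normal arrays were not left out in turn for this list, so its dependence on a single normal array is open. With an estimated correlation the list was not called (adjusted p = 0.152), and 10 splits are too few to exclude chance. An effect of the injury or of the surgery, or a difference between the mice of both groups, may be behind it, and none of these was tested.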
